A study of Mus musculus with 6 samples.

How the data were processed

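RNA was measured in sorted tuft cells of mouse small intestine at day 0, day 6 and day 14, with 2 libraries per day. Per the labels' protocols, total RNA was extracted with TRIzol, and libraries were made by SMART-seq type cDNA amplification followed by transposase-based construction. Such libraries do not mark strand. The labels give the genotype as wild type, and the series text gives the sorting gate as EpCAM+ SiglecF+. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT and the build mm10 were used. The read counter, the gene annotation and the role of each aligner are not given in the sources used here.

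The deposited table held 17105 genes for 6 libraries, 17048 of them protein-coding. Per the file headers, its read count columns hold reads per gene. These deposited values are estimated counts, because 19.1% to 19.9% of the values per library were not whole (tolerance 0.01). The deposited TPM columns, made by the authors, summed to 1000000 per library, and the deposited FPKM columns are fragments scaled by gene length and library size, per the file headers. The deposited normalized read count columns are a signal in which the estimated counts were rounded up and divided by a size factor per library. The authors' averages per day were not used here, nor were TPM and FPKM. The normalized values served for an alternative set of whole counts. Totals were 17037200 and 18176480 estimated counts at day 0, 21693257 and 22399995 at day 6, and 17215768 and 19460205 at day 14.

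The estimated counts were rounded to whole numbers for the test. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 13114 genes with 99.96% of the counts. edgeR 4.0.16 was used with TMM factors and the quasi-likelihood test, with all 6 libraries in the fit, the day as the factor and 3 residual degrees of freedom. Day 6 against day 0, day 14 against day 0 and day 14 against day 6 were tested, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with calls at 0.05. Day was taken from the sample titles. The common dispersion was 0.0286, a biological coefficient of variation of 0.169. Values in CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD over 2 libraries, and SE is that of the log2 fold change.

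The test, its samples, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 32 lists held 804 entries for 752 distinct genes, of which 761 entries were found, 5 of them by an older symbol, and 46 genes were in more than 1 list. Lists cover tuft cell identity and subtypes, chemosensing, eicosanoids, acetylcholine, cytokine signalling, IL-13 and interferon responses, antigen presentation, repair, antimicrobial peptides, cell cycle, ribosome, respiration, glycolysis, cholesterol, the unfolded protein response, stress genes and markers of other cell types. The B and plasma cell list had under 5 tested members and was not tested. Camera of limma 3.58.1 was run on 31 lists with a preset correlation of 0.01, then with an estimated correlation, beside fry, with Benjamini-Hochberg adjustment over 93 list tests. Camera called 55 of them with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.298), and fry called 4. With an estimated correlation, camera also takes its p from the 3 residual degrees of freedom. A lost call is therefore no measure of correlation alone. For eicosanoid genes at day 6 the estimate was 0.02, near the preset, yet the unadjusted camera p went from 1.22e-06 to 0.0192. For granulocyte markers at day 14 against day 0 it was -0.111, below the preset, and that p went from 0.00102 to 0.0435. Camera sets a list against the other genes. The test by fry asks whether a list's genes move on balance 1 way, and compares them with no other genes.

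Named genes were, for each comparison with day 0, the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean of at least 20 CPM in the higher group and groups that do not overlap. Unnamed gene models and antigen receptor segments were left out. From each list, up to 3 called members with the smallest adjusted p and a mean of at least 5 CPM were added. For day 14 against day 6 the numbers were 5, 5 and 1. A fixed set of genes, most but not all of them tuft cell genes, was added called or not, and not all of that set are in the text. Members named only to complete a count of 5 or fewer were chosen after their values were seen, and for those no values with a library left out are given. The rule named 52 called genes for day 6 against day 0, 81 for day 14 against day 0 and 28 for day 14 against day 6, of which 20, 38 and 5 kept their call whichever library was left out. Not all of them are in the text, and for the comparisons with day 0 those that kept the call are in it more often. Coordinates are of GENCODE M21 on mm10, matched by gene identifier, and 17064 identifiers had a name there. Where a group had 0 counts, a floor of 3 counts over the group gave a lower bound, and with 1 to 3 counts an exact 95% counting interval was computed.

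The test was tested on simulated counts with 100 genes changed by each of 2 fold sizes. Of genes changed 2-fold, 79% were recovered for day 6 against day 0, 67% for day 14 against day 0 and 74% for day 14 against day 6, and 100% of those changed 4-fold in each. False calls were 26 of 205, 15 of 182 and 12 of 186, above the nominal share. Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of 5 CPM in 2 libraries, only the days compared, the replicate number as a block, abundant and mitochondrial genes left out, a 2-fold threshold and each library left out in turn. Counts rounded up and the Paneth marker level as a covariate were added after the data were seen. Shared controls were simulated 40 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.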

Results

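RNA sequencing was performed on tuft cells, the rare chemosensory cells of the intestinal epithelium that release IL-25, sorted as EpCAM+ SiglecF+ cells from the small intestine of wild-type mice. Cells were collected at day 0, day 6 and day 14 of infection with Heligmosomoides polygyrus, a roundworm of the small intestine that evokes type 2 immunity. Each day was represented by 2 libraries, 6 in all. The treatment label names the infection in all 6 libraries, day 0 included, and the sample titles give the days, so day 0 was taken as the naive state that the series title names. The labels do not say whether the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical. The libraries held 17037200 and 18176480 estimated counts at day 0, 21693257 and 22399995 at day 6, and 17215768 and 19460205 at day 14. Of 17105 genes in the table, 13114 had enough counts to be tested. The biological coefficient of variation across the 3 days was 0.169, and the first principal component, with 42.7% of the variance, set both day 14 libraries apart from the other 4.

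The tuft cell genes were abundant on every day. Epcam, one of the sorting antigens, stood at 2005 ± 167 CPM at day 0, 2504 ± 163 at day 6 and 2339 ± 188 at day 14 (SD, n = 2), and Siglecf, the other, at 1227 ± 281, 1834 ± 91.0 and 1221 ± 305 CPM. Trpm5, the taste-type cation channel, stood at 2254 ± 90.7, 2183 ± 73.4 and 1763 ± 64.8 CPM, and Il25, the cytokine that starts the type 2 circuit, at 37.8 ± 10.8, 48.5 ± 2.50 and 29.0 ± 3.21 CPM. None of these 4 passed the test in any comparison, nor did Pou2f3, the transcription factor that specifies tuft cells, or Chat, which makes acetylcholine. Genes of other cells were present as well and differed between libraries. The mean log2(CPM + 0.5) of 26 enterocyte markers was 8.60 and 8.66 in the day 0 libraries, 7.27 and 7.59 at day 6, and 7.49 and 7.44 at day 14. That of 18 Paneth cell markers was 5.52 in day 0 replicate 1 and 7.92 in day 0 replicate 2, against 4.85 and 5.01 at day 6 and 7.29 and 7.11 at day 14. Mitochondrially encoded genes took 4.76% and 3.97% of the counts at day 0, 4.33% and 5.57% at day 6, and 8.29% and 9.31% at day 14.

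**Figure D1:**
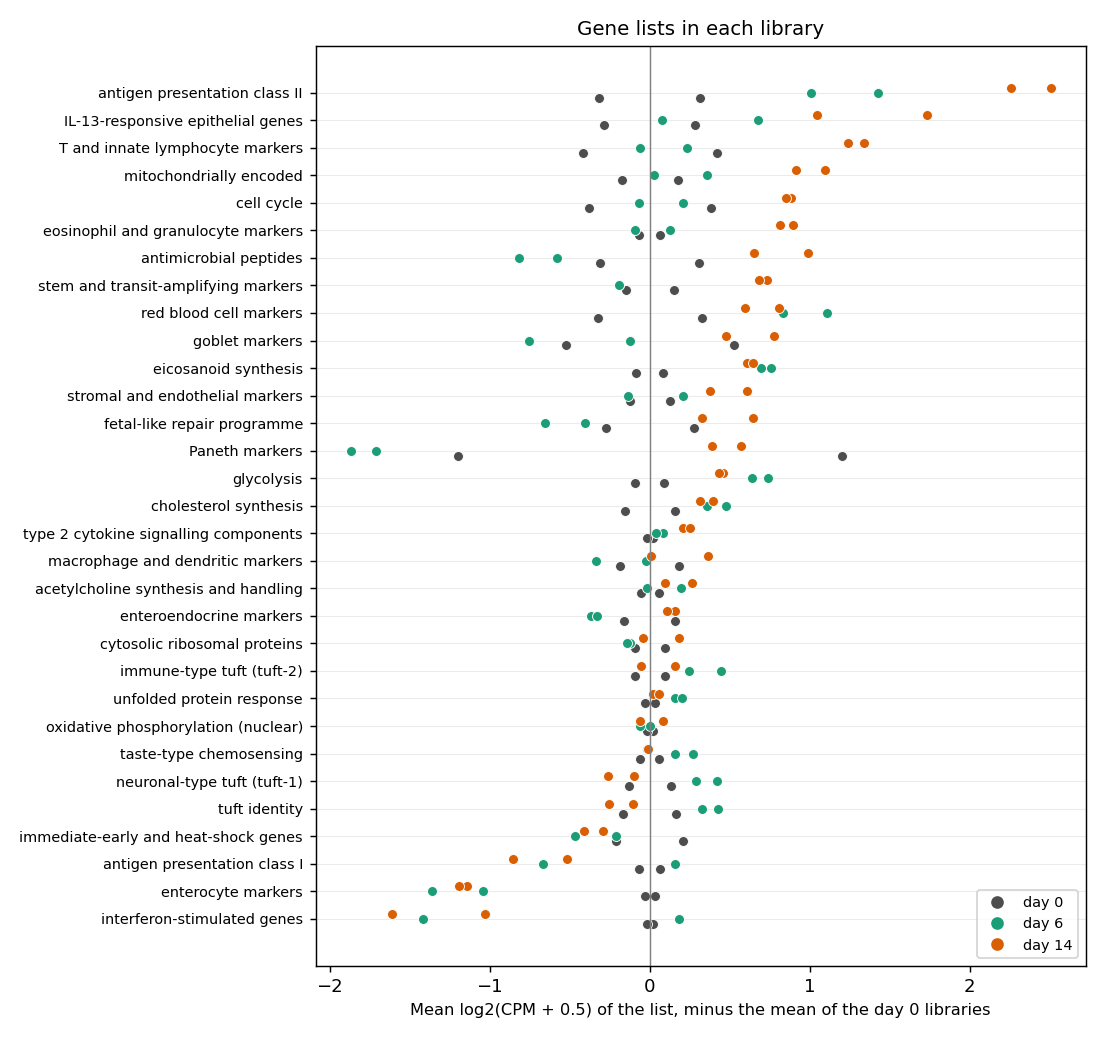
Mean log2(CPM + 0.5) of each gene list with at least 5 tested members in each of the 6 libraries, minus the mean of the day 0 libraries (x axis, log2 units), with 1 point per library, coloured by day, and lists on the y axis ordered by their day 14 mean. Class II antigen presentation genes lie highest at day 14, the interferon-stimulated genes differ between the day 6 libraries (6.78 and 5.18), and the Paneth markers differ between the day 0 libraries (5.52 and 7.92).

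The first comparison asked how tuft cells differed from the naive state at day 6. Camera called the lists of MHC class II antigen presentation, eicosanoid synthesis and glycolysis genes higher at day 6, and each call was lost with an estimated correlation (adjusted p = 0.346, 0.298 and 0.434). That setting rests on 3 residual degrees of freedom and called no list in any comparison, so such losses are no measure of correlation alone. H2-Ab1, a class II beta chain gene on chromosome 17 (34257689 to 34269419), rose from 13.5 ± 1.64 to 54.4 ± 1.82 CPM (SD, n = 2), a log2 fold change of 2.0 ± 0.15 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0035). Cd74, the class II invariant chain, rose from 21.6 ± 7.26 to 78.6 ± 6.88 CPM. Of the 8 class II genes tested, 3 rose (H2-DMa was the other) and 1, the cathepsin gene Ctss, fell, against 6 and 1 adjusted over the list alone. The camera test called the list higher (adjusted p = 3.49e-09), and the call was lost with an adjusted p = 0.346 with an estimated correlation. Ctss lost its call without day 6 replicate 2 (edgeR adjusted p = 0.0822). In the same libraries, the median log2 fold change was -1.13 for enterocyte markers and -2.47 for Paneth markers (-3.16 and -0.95 without day 0 replicates 1 and 2).

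Of 14 eicosanoid synthesis genes, 4 rose at day 6, and 8 rose and 1 fell adjusted over the list alone. By camera, the list was called higher (adjusted p = 4.2e-06; adjusted p = 0.298 with an estimated correlation). Pla2g4c, a cytosolic phospholipase A2, rose from 0.68 ± 0.21 to 14.4 ± 3.85 CPM (SD, n = 2), a log2 fold change of 4.42 ± 0.63 (SE). Alox5ap, the activating protein of 5-lipoxygenase, rose from 610 ± 169 to 1361 ± 16.8 CPM (edgeR adjusted p = 0.0147; 0.0587 without day 6 replicate 1). Ptgs2, an inducible prostaglandin synthase, rose by 1.30 log2 units, and its edgeR adjusted p was 0.0802 without day 0 replicate 2, 0.0592 without day 6 replicate 1 and 0.088 without day 6 replicate 2. The other member that rose was the phospholipase gene Pla2g4a, which was named after its values were seen. Alox5, Ltc4s and Hpgds, which make leukotrienes and prostaglandin D2, had log2 fold changes of 0.34, 0.20 and 0.62 and did not pass. Enterocyte markers had a median log2 fold change of -1.13 in the same libraries.

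Of 18 glycolysis genes, 12 rose and 1 fell at day 6 (15 and 1 adjusted over the list alone). Pgk1, phosphoglycerate kinase, rose from 271 ± 53.9 to 655 ± 12.8 CPM (SD, n = 2; edgeR adjusted p = 0.00609), and Aldoc, an aldolase, rose by 1.40 log2 units. The camera test called the list higher (adjusted p = 1.23e-13; adjusted p = 0.434 with an estimated correlation). Of 23 cholesterol synthesis genes, 2 rose, Tm7sf2 and Fdps, against 13 adjusted over the list alone (camera adjusted p = 9.15e-07; adjusted p = 0.502 with an estimated correlation). Tm7sf2 lost its call without day 0 replicate 2, day 6 replicate 1 or day 6 replicate 2 (edgeR adjusted p = 0.0872, 0.0759 and 0.0828). Fdps lost its call without any 1 library other than day 0 replicate 1, with an edgeR adjusted p of 0.117 without day 0 replicate 2, 0.109 and 0.153 without day 6 replicates 1 and 2, and 0.0557 and 0.0564 without day 14 replicates 1 and 2. Beside both lists, the median log2 fold change was -1.13 for enterocyte markers and -2.47 for Paneth markers (-3.16 and -0.95 without day 0 replicates 1 and 2). Bnip3, a mitophagy receptor, rose from 18.7 ± 6.41 to 68.7 ± 4.14 CPM, and Scd2, a stearoyl-CoA desaturase, from 48.9 ± 6.70 to 152 ± 11.1 CPM.

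Among tuft cell genes, Sucnr1, the succinate receptor, rose from 39.4 ± 3.07 to 88.3 ± 0.71 CPM at day 6 (SD, n = 2), a log2 fold change of 1.16 ± 0.16 (SE; edgeR adjusted p = 0.00989). Ptprc, which encodes CD45, rose by 0.84 log2 units (edgeR adjusted p = 0.0127; 0.0676 without day 6 replicate 1). In the same libraries, enterocyte markers had a median log2 fold change of -1.13 and Paneth markers one of -2.47 (-3.16 and -0.95 without day 0 replicates 1 and 2). Of 35 tuft identity genes, 2 rose, Alox5ap and Skap2, and 8 did adjusted over the list alone (camera adjusted p = 4.2e-06; adjusted p = 0.549 with an estimated correlation). Alox5ap had an edgeR adjusted p of 0.0587 without day 6 replicate 1, and Skap2 had one of 0.16 without day 0 replicate 2, 0.168 and 0.13 without day 6 replicates 1 and 2, and 0.0604 and 0.0614 without day 14 replicates 1 and 2. In the neuronal-type tuft list, 1 of 16 genes rose, Tmem176a, against 5 adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.548 with an estimated correlation). Tmem176a had an edgeR adjusted p of 0.0636 without day 0 replicate 2, 0.114 and 0.0855 without day 6 replicates 1 and 2, and 0.0504 without day 14 replicate 2. In the immune-type list, 2 of 23 genes rose, Alox5ap and Ptprc, against 10 adjusted over the list alone (camera adjusted p = 1.71e-05; adjusted p = 0.502 with an estimated correlation). For taste-type chemosensing, 1 of 15 genes, Sucnr1, rose and 4 did adjusted over the list alone (camera adjusted p = 0.0342; adjusted p = 0.502 with an estimated correlation). That call was lost without day 0 replicate 2 (camera adjusted p = 0.103) and without day 6 replicate 1 (0.144). Dclk1, a tuft cell kinase, and Il17rb, the IL-25 receptor, had log2 fold changes of 0.25 and 0.22 and did not pass.

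Genes of the epithelial response to IL-13 were split at day 6: 3 of 23 rose, Gsdmc2, Gsdmc4 and Pla2g4c, and 1, Itln1, fell, against 7 and 1 adjusted over the list alone. Gsdmc2, a gasdermin gene on chromosome 15 (63824346 to 63845177), rose from 4.73 ± 0.89 to 27.2 ± 7.71 CPM (SD, n = 2; edgeR adjusted p = 0.00904). Gsdmc4 rose by 1.73 log2 units, with an edgeR adjusted p of 0.0606 without day 0 replicate 1 and 0.125 without day 6 replicate 2. The Gsdmc genes are near-identical copies, so the split of reads among them is uncertain. By camera, the list was called higher (adjusted p = 0.0342; adjusted p = 0.742 with an estimated correlation), lost the call without day 6 replicate 2 (0.562) and turned its direction without day 0 replicate 1 (0.466). For acetylcholine handling, 1 of 9 genes rose and 2 fell, against 3 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.787; median log2 fold change -0.12, mean 0.14, direction of the test down). The riser, Slc18a3, lies inside Chat on the same strand, so its log2 fold change of 2.87 is uncertain. The genes that fell were the choline kinases Chka, with an edgeR adjusted p of 0.0599 without day 0 replicate 2 and 0.0901 without day 6 replicate 1, and Chkb, with one of 0.2 without day 6 replicate 2, 0.151 without day 0 replicate 2, 0.145 without day 6 replicate 1, and 0.0626 and 0.0636 without day 14 replicates 1 and 2.

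Enterocyte genes were lower at day 6: 21 of 26 fell and 0 rose, and 24 fell and 1 rose adjusted over the list alone. Anpep, the brush border aminopeptidase N gene on chromosome 7 (79821803 to 79861059), fell from 1511 ± 95.7 to 429 ± 100 CPM (SD, n = 2), a log2 fold change of -1.82 ± 0.17 (SE; edgeR adjusted p = 0.0048). Apoc3, an apolipoprotein, had a log2 fold change of -1.48. The camera test called the list lower (adjusted p = 4.96e-34; adjusted p = 0.298 with an estimated correlation). By fry, which tests whether a list's genes move on balance 1 way and compares them with no other genes, the adjusted p was 0.0477. Fabp6, the ileal bile acid binding protein, stood at 104 and 474 CPM in the day 0 libraries and 0.33 and 7.45 CPM at day 6. Its log2 fold change was -6.20 ± 1.05 (edgeR adjusted p = 0.018), -6.91 without day 0 replicate 1, -4.73 without day 0 replicate 2, -5.28 without day 6 replicate 1 and -9.73 without day 6 replicate 2.

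Paneth cell genes were called lower at day 6, by an amount that depended on day 0 replicate 2. Of 18 Paneth markers, 9 fell, and 15 did adjusted over the list alone (camera adjusted p = 8.24e-11; adjusted p = 0.502 with an estimated correlation). The list's median log2 fold change was -2.47, with a range of -3.16 without day 0 replicate 1 to -0.95 without day 0 replicate 2. Lyz1, Paneth cell lysozyme, fell by 2.25 log2 units, by 0.91 without day 0 replicate 2 and by 2.93 without day 0 replicate 1, and its edgeR adjusted p of 0.0443 became 0.154 and 0.148 without day 6 replicates 1 and 2, and 0.0747 and 0.0768 without day 14 replicates 1 and 2. Reads of the defensin genes, a family of near-identical copies, cannot be divided among members with certainty. In the antimicrobial peptide list, 5 of 15 genes fell, Reg3b, Reg3g, Reg3a, Reg4 and Lyz1, against 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000422; adjusted p = 0.346 with an estimated correlation). Reg3g, a C-type lectin that kills bacteria, fell from 476 ± 40.8 to 137 ± 60.6 CPM (SD, n = 2), and Reg3a lost its call without day 6 replicate 1 (edgeR adjusted p = 0.077).

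Interferon-stimulated genes had a median log2 fold change of -0.41 at day 6, which was -1.43 without day 6 replicate 1 and 0.12 without day 6 replicate 2. Over all genes or adjusted over the list alone, 0 of 38 passed. The camera test called them lower (adjusted p = 0.00216; adjusted p = 0.742 with an estimated correlation) and called them higher without day 6 replicate 2 (0.0467). Immediate-early and heat-shock genes, which respond to cell handling, were called lower (camera adjusted p = 0.0101; adjusted p = 0.502 with an estimated correlation), and the call was lost without day 0 replicate 2 (0.195) and day 6 replicate 1 (0.113). Of their 26 members, 3 fell, Jun, Fos and Atf3, against 5 adjusted over the list alone. Jun had an edgeR adjusted p of 0.14 without day 6 replicate 1, 0.0938 without day 0 replicate 2 and 0.0682 without day 6 replicate 2. Fos had one of 0.18 without day 6 replicate 1, 0.152 without day 0 replicate 2, and 0.0593 and 0.0604 without day 14 replicates 1 and 2. Atf3 had one of 0.107 without day 0 replicate 2, 0.106 without day 6 replicate 1 and 0.095 without day 6 replicate 2. Goblet markers, with 0 of 15 past the test both ways, were called lower (camera adjusted p = 0.0435; adjusted p = 0.742 with an estimated correlation), lost the call without day 6 replicate 1 (0.55) and turned without day 0 replicate 2 (0.554). Ribosomal protein genes, with 0 of 76 past the test both ways, were called lower (camera adjusted p = 0.032; adjusted p = 0.865 with an estimated correlation), and the call was lost without day 0 replicate 2 (0.718), day 6 replicate 1 (0.0563) and day 6 replicate 2 (0.0972). Red blood cell genes, with 0 of 5 past the test and 4 higher adjusted over the list alone, were called higher (camera adjusted p = 0.000321; adjusted p = 0.498 with an estimated correlation).

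The other lists were not called at day 6. Camera adjusted p was 0.528 for the type 2 cytokine components, the cell cycle and the stem cell markers, 0.0638 for class I antigen presentation, 0.0529 for the fetal-like repair genes, 0.0628 for the unfolded protein response, 0.187 for mitochondrially encoded genes and 0.2 for enteroendocrine markers. It was 0.751 for nuclear oxidative phosphorylation genes (median 0.002, mean -0.025, test down), 0.478 for eosinophil and granulocyte markers (median -0.32, mean -0.17, test up), 0.707 for stromal markers (median -0.07, mean 0.19, test up), 0.706 for lymphocyte markers and 0.417 for macrophage markers. In the granulocyte list, Kit, a receptor of stem cell factor that mast cells carry, rose from 26.3 ± 0.44 to 53.5 ± 3.63 CPM (SD, n = 2; edgeR adjusted p = 0.00609). The mast cell protease gene Mcpt1 of that list had 1 count at day 0 and 1 at day 6. Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 242 genes higher and 353 lower at day 6, of which 103 and 191 changed at least 2-fold. These counts were 563 and 497 without day 0 replicate 1, 60 and 165 without day 0 replicate 2, 54 and 132 without day 6 replicate 1, 48 and 160 without day 6 replicate 2, and 158 and 256 without day 14 replicate 2.

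**Figure D2:**
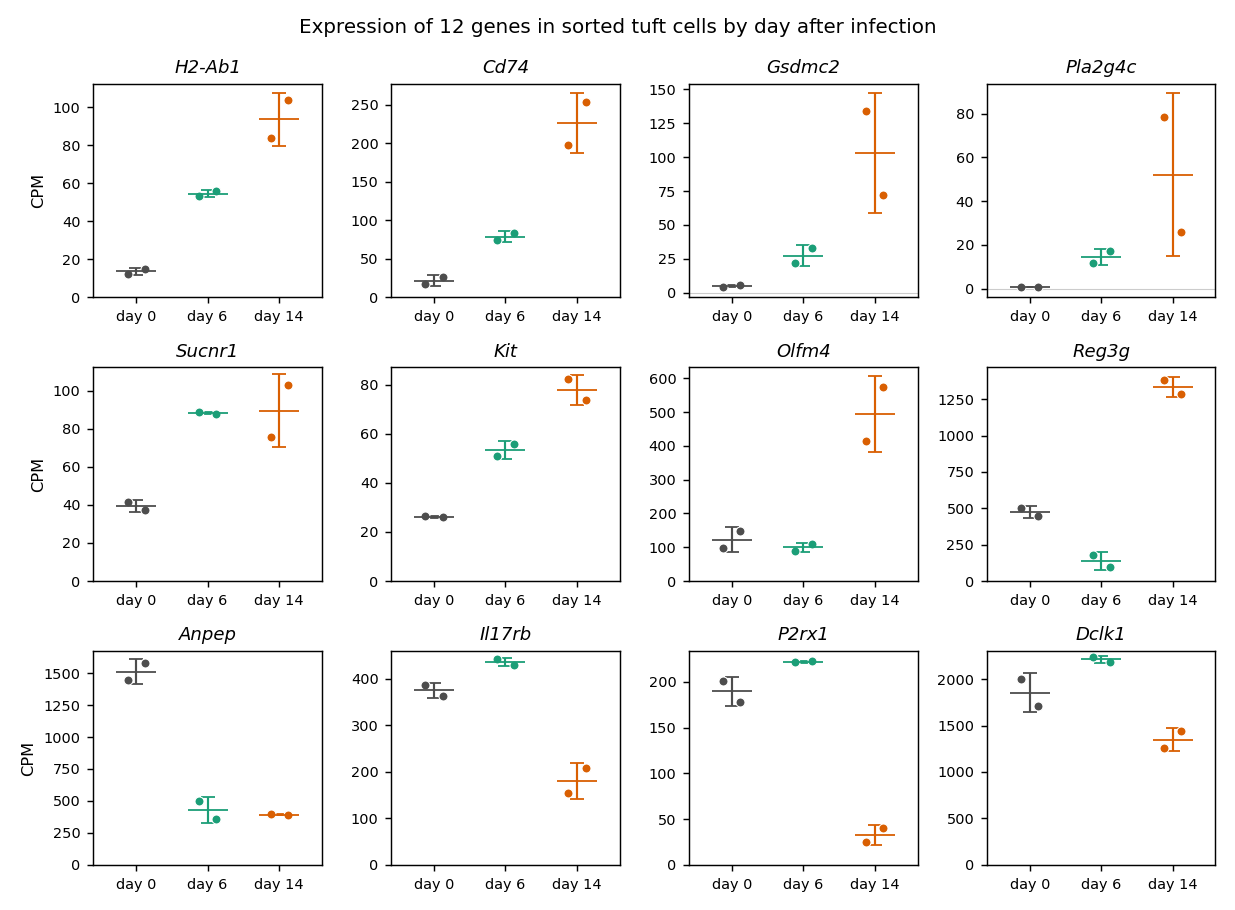
Level of 12 genes in CPM (linear y axes from 0) at day 0, day 6 and day 14 (x axis), with points for the libraries, a horizontal line for the mean and bars for the SD (n = 2). H2-Ab1 stood at 13.5, 54.4 and 93.7 CPM on the 3 days and P2rx1 at 190 CPM at day 0 and 32.8 CPM at day 14.

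The comparison of day 14 with day 0 asked how tuft cells differed from the naive state later in infection. Gkn1 and the crypt base gene Olfm4 rose, and P2rx1, a tuft cell gene, fell. Camera called the class II list higher and the enterocyte list lower at day 14, and both calls were lost with an estimated correlation (adjusted p = 0.298 for each). Cd74, on chromosome 18 (60803848 to 60812652), rose from 21.6 ± 7.26 to 226 ± 39.0 CPM (SD, n = 2), a log2 fold change of 3.38 ± 0.24 (SE; edgeR adjusted p = 0.000774). H2-Ab1 rose to 93.7 ± 13.9 CPM, a log2 fold change of 2.79 ± 0.16, and H2-Eb1, another class II beta chain, from 4.99 ± 0.75 to 31.01 ± 3.32 CPM. Of the 8 class II genes, 6 rose and 0 fell, against 7 and 1 adjusted over the list alone. By camera, the list was called higher (adjusted p = 1.81e-19; adjusted p = 0.298 with an estimated correlation), and the adjusted p by fry was 0.0487. Leukocytes carry class II as well. In the same day 14 libraries, T and innate lymphocyte markers had a median log2 fold change of 1.56 (2.54 without day 0 replicate 2). The mast cell protease gene Mcpt1 had 187 counts against 1 at day 0, and Ctsc, a macrophage list gene, rose from 82.2 to 279 CPM.

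Gkn1, Gkn2 and Tff1, which surface mucous cells of the stomach express, and Tff2, a gene of its mucous neck and antral gland cells, were at or near 0 at day 0 and detected at day 14. Gkn1, a gastrokine gene with identifier ENSMUSG00000030050 on chromosome 6 (87345650 to 87350942), had 0 counts in the day 0 libraries and 926 at day 14, at least 297-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00108). Gkn2, its neighbour, had 0 and 1921 counts, at least 612-fold higher, and Tff2, a trefoil factor, 0 and 1409 counts, at least 460-fold higher. Tff1, another trefoil factor, rose from 0.26 ± 0.29 to 47.0 ± 25.3 CPM (SD, n = 2), a log2 fold change of 7.51 that was 9.63 without day 0 replicate 1, 6.63 without day 0 replicate 2 and 6.81 without day 14 replicate 2. Gkn1 stood at 18.1 and 31.5 CPM in the day 14 libraries, and Gkn2 at 30.97 and 71.4 CPM. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

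**Figure D3:**
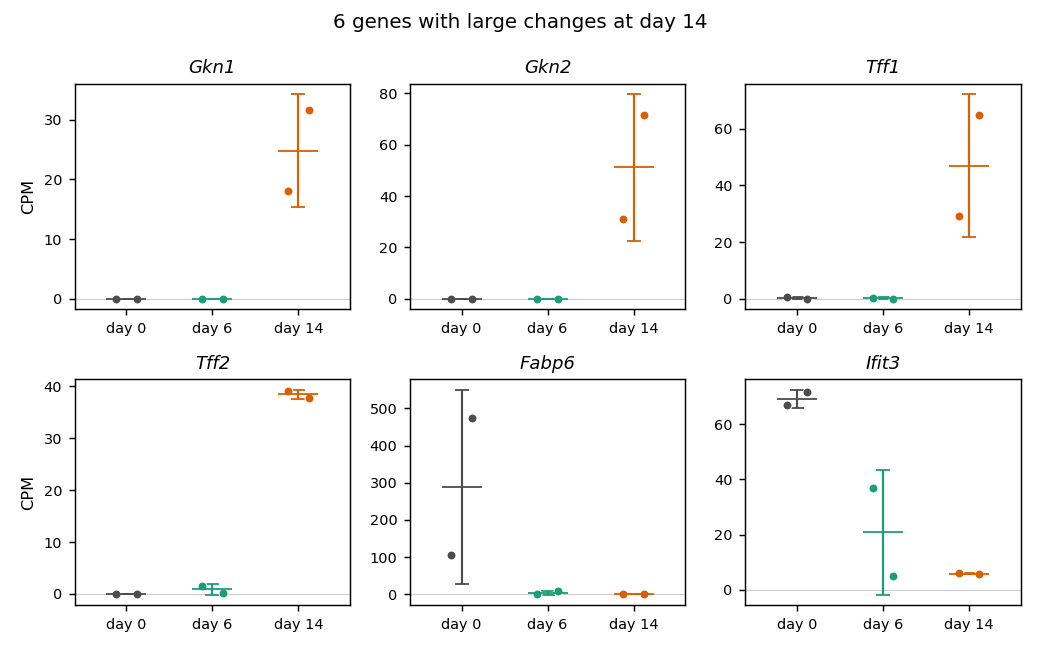
Level of 6 genes with large changes at day 14, in CPM (linear y axes from 0), at day 0, day 6 and day 14 (x axis), with points for the libraries, a horizontal line for the mean and bars for the SD (n = 2). Gkn1 stood at 0 CPM at day 0 and 24.9 CPM at day 14, and Ifit3 differed between the day 6 libraries (37.0 and 4.89 CPM).

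Of 23 IL-13-responsive genes, 10 rose at day 14, 1, Spdef, fell and 12 did not pass over all genes, against 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.1e-09; adjusted p = 0.502 with an estimated correlation). Gsdmc2 rose from 4.73 ± 0.89 to 103 ± 44.1 CPM (SD, n = 2), a log2 fold change of 4.44 ± 0.35 (SE; edgeR adjusted p = 0.000952). Gsdmc4 and Gsdmc3 rose by 3.42 and 3.62 log2 units, the latter by 4.33 without day 0 replicate 2, with reads again uncertain among these copies. Pla2g4c rose to 52.0 ± 37.3 CPM, a log2 fold change of 6.26 that was 5.25 without day 14 replicate 1 and 6.85 without day 14 replicate 2. Spdef, a transcription factor of goblet cells, lost its call without day 0 replicate 1 (edgeR adjusted p = 0.0646), day 0 replicate 2 (0.0777) and day 14 replicate 2 (0.165). In the same day 14 libraries, the median log2 fold change was 1.56 for lymphocyte markers (2.54 without day 0 replicate 2) and -0.98 for enterocyte markers. Mitochondrially encoded genes took 8.29% and 9.31% of the counts, against 4.76% and 3.97% at day 0. These values stand beside the eicosanoid list as well. Of its 14 genes, 3 rose, Pla2g4c, Alox5ap and Pla2g4a, with 3 adjusted over the list alone (camera adjusted p = 0.0133; adjusted p = 0.434 with an estimated correlation), and the list's call was lost without day 0 replicate 2 (0.0975). Alox5ap had an edgeR adjusted p of 0.171 without day 14 replicate 2, 0.0971 without day 14 replicate 1, 0.0587 without day 0 replicate 2 and 0.0505 without day 6 replicate 1. Pla2g4a had one of 0.228 without day 14 replicate 2, 0.0561 without day 14 replicate 1, 0.122 without day 0 replicate 2 and 0.0532 without day 6 replicate 1.

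Among genes of the crypt base, Olfm4 rose at day 14 from 123 ± 35.7 to 494 ± 112 CPM (SD, n = 2), a log2 fold change of 2.01 ± 0.23 (SE; edgeR adjusted p = 0.0032). Of 13 stem and transit-amplifying markers, 5 rose, Olfm4, Slc12a2, Smoc2, Gkn3 and Cdca7, and 6 did adjusted over the list alone (camera adjusted p = 4.45e-05; adjusted p = 0.346 with an estimated correlation). Of 42 cell cycle genes, 14 rose and 0 fell, and 29 rose adjusted over the list alone. Camera called the list higher (adjusted p = 1.99e-13, and 0.502 with an estimated correlation). Its median log2 fold change was 0.885, and 0.468 to 1.405 with 1 library left out. Its mean log2(CPM + 0.5) already differed between day 0 replicates 1 and 2 (3.33 and 4.09), against 4.59 and 4.56 at day 14. Rrm1, a ribonucleotide reductase subunit, rose from 16.0 ± 3.44 to 38.7 ± 2.54 CPM, and Mki67, a marker of cycling cells, had a log2 fold change of 0.62 and did not pass. Kif11, a mitotic kinesin, rose by 1.46 log2 units, with an edgeR adjusted p of 0.0606 without day 0 replicate 1, and 0.0725 and 0.102 without day 14 replicates 1 and 2. Mcm5, a replication helicase subunit, rose by 1.08, with one of 0.0509 without day 0 replicate 1, and 0.0829 and 0.0845 without day 14 replicates 1 and 2. In the same libraries, lymphocyte markers had a median log2 fold change of 1.56 (2.54 without day 0 replicate 2), and enterocyte markers one of -0.98. Mitochondrially encoded genes took 8.29% and 9.31% of the counts at day 14, against 4.76% and 3.97% at day 0. In the fetal-like repair list, 7 of 18 genes rose and 1, Ly6e, fell, against 9 and 3 adjusted over the list alone (camera adjusted p = 0.00313; adjusted p = 0.549 with an estimated correlation). That call was lost without day 0 replicate 1 (0.141), day 6 replicate 1 (0.0563) and day 6 replicate 2 (0.0594). Clu, clusterin, rose by 2.18 log2 units and Krt7, a keratin, by 1.23. Ly6e had an edgeR adjusted p of 0.0634 and 0.0524 without day 0 replicates 1 and 2, and 0.168 and 0.182 without day 14 replicates 1 and 2.

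Mitochondrially encoded genes all rose at day 14, 13 of 13 over all genes and adjusted over the list alone (camera adjusted p = 1.45e-11; adjusted p = 0.434 with an estimated correlation). mt-Cytb rose by 1.26 log2 units, and its edgeR adjusted p of 0.00772 became 0.064 without day 14 replicate 2, when that of mt-Atp6 was 0.0666 and that of mt-Nd1 0.0702. Nuclear oxidative phosphorylation genes did not move with them, with 0 of 75 past the test both ways (camera adjusted p = 0.944). Lymphocyte markers had a median log2 fold change of 1.56 in these libraries (2.54 without day 0 replicate 2), and enterocyte markers one of -0.98. Of 18 glycolysis genes, 4 rose, Pgk1 and Pkm among them, against 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000804; adjusted p = 0.548 with an estimated correlation). Pgk1 had an edgeR adjusted p of 0.0774 without day 14 replicate 2. Hk2, a hexokinase, rose by 1.41 log2 units (2.05 without day 0 replicate 2), with an edgeR adjusted p of 0.0676 without day 0 replicate 1, and 0.0906 and 0.156 without day 14 replicates 1 and 2. Pfkl, a phosphofructokinase, rose by 0.52, with one of 0.12 without day 0 replicate 2, 0.0597 and 0.0574 without day 6 replicates 1 and 2, and 0.108 and 0.163 without day 14 replicates 1 and 2. Of 23 cholesterol synthesis genes, 4 rose, Hmgcs1, Idi1, Sc5d and Cyp51, and 5 did adjusted over the list alone (camera adjusted p = 0.00108; adjusted p = 0.593 with an estimated correlation), and the call was lost without day 0 replicate 2 (0.0889). Without day 0 replicate 2 and day 14 replicate 2, the edgeR adjusted p was 0.0656 and 0.16 for Hmgcs1 (log2 fold change 1.08), 0.0997 and 0.194 for Idi1 (0.86) and 0.14 and 0.224 for Sc5d (0.69). Sc5d also lost its call without day 6 replicates 1 and 2 (0.0584 and 0.0504) and day 14 replicate 1 (0.0629). Of 15 antimicrobial genes, 5 rose, Reg3g, Retnlb, Duox2, Duoxa2 and Pigr, and 2 fell, Reg3a and Saa3, against 6 and 2 adjusted over the list alone (camera adjusted p = 0.0162; adjusted p = 0.434 with an estimated correlation). The list lost its call without day 0 replicate 1 (0.205) and day 14 replicate 1 (0.0552). Reg3g rose from 476 ± 40.8 to 1333 ± 69.5 CPM (SD, n = 2; edgeR adjusted p = 0.012), with an adjusted p of 0.0574 without day 14 replicate 1 and 0.0702 without day 14 replicate 2. Reg3a had an edgeR adjusted p of 0.0668 without day 0 replicate 1, 0.0953 without day 14 replicate 1 and 0.135 without day 14 replicate 2.

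A lymphocyte list and an eosinophil and granulocyte list that also holds mast cell genes were called higher at day 14. An EpCAM+ SiglecF+ gate would largely remove such cells. Both calls were lost with an estimated correlation (adjusted p = 0.434 and 0.346). Of 16 T and innate lymphocyte markers, 6 rose and 9 did adjusted over the list alone (camera adjusted p = 2.21e-07; adjusted p = 0.434 with an estimated correlation). Gzma, granzyme A, rose from 5.82 ± 2.58 to 32.9 ± 6.86 CPM (SD, n = 2), a log2 fold change of 2.49 ± 0.30 (SE; edgeR adjusted p = 0.00384). Ccl5, a chemokine, rose by 1.94 log2 units (2.60 without day 0 replicate 2), with an edgeR adjusted p of 0.0537 and 0.0519 without day 14 replicates 1 and 2. Gzmb, granzyme B, rose by 2.36 (1.74 and 3.54 without day 0 replicates 1 and 2), with one of 0.0506 and 0.142 without day 14 replicates 1 and 2. Of 6 genes of the eosinophil and granulocyte list, 3 rose, the mast cell genes Mcpt1, Mcpt2 and Kit, and 1 fell, Cxcr2. Adjusted over the list alone, the counts were the same. Camera called the list higher (adjusted p = 0.00237, and 0.346 with an estimated correlation), and the adjusted p by fry was 0.0477. Its median log2 fold change was 0.365 and its mean 1.85, so the call rests on mast cell genes and not on granulocyte markers in general. Kit rose from 26.3 ± 0.44 to 78.0 ± 6.14 CPM. Mcpt1, a mast cell protease of the mucosa, had 1 count at day 0, in day 0 replicate 2, and 187 at day 14, a ratio of 183 (95% exact counting interval 32.4 to 7260). Cxcr2 lost its call without day 0 replicate 1 (edgeR adjusted p = 0.058), day 0 replicate 2 (0.053), day 14 replicate 1 (0.0953) and day 14 replicate 2 (0.129). Red blood cell genes, with 0 of 5 past the test both ways, were called higher (camera adjusted p = 0.039; adjusted p = 0.593 with an estimated correlation), and the call was lost without day 0 replicate 2 (0.273) and day 14 replicate 2 (0.101).

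Enterocyte genes stayed lower at day 14, with 20 of 26 below day 0 and 1, Fabp1, above it (23 and 1 adjusted over the list alone). Anpep fell to 394 ± 5.09 CPM (SD, n = 2), a log2 fold change of -1.94 ± 0.17 (SE; edgeR adjusted p = 0.00108), and Apoc3 fell by 2.0 log2 units. The camera test called the list lower (adjusted p = 7.42e-21; adjusted p = 0.298 with an estimated correlation), and the adjusted p by fry was 0.0487. Beside this fall, lymphocyte markers had a median log2 fold change of 1.56 (2.54 without day 0 replicate 2). Mitochondrially encoded genes took 8.29% and 9.31% of the counts at day 14, against 4.76% and 3.97% at day 0. Fabp6 stood at 0.23 and 0.88 CPM at day 14, a log2 fold change of -8.97 (edgeR adjusted p = 0.0065). It was -9.69 without day 0 replicate 1 and -7.50 without day 0 replicate 2, and its adjusted p was 0.0549 without day 14 replicate 1 (log2 fold change -8.36) and 0.0686 without day 14 replicate 2 (-10.25).

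Several tuft cell genes were lower at day 14 and others higher. P2rx1, an ATP-gated channel, fell from 190 ± 16.1 to 32.8 ± 10.7 CPM (SD, n = 2), a log2 fold change of -2.53 ± 0.21 (SE; edgeR adjusted p = 0.00108). Il17rb fell from 375 ± 16.0 to 181 ± 38.7 CPM, a log2 fold change of -1.05 ± 0.16, and Matk, a kinase gene, from 5254 ± 187 to 2438 ± 157 CPM. Plcb2, the phospholipase of taste signalling, had a log2 fold change of -0.84, while Sucnr1, Ptprc and Vmn2r26, a vomeronasal-type receptor, rose by 1.18, 1.24 and 1.21 log2 units. Ptprc encodes CD45, which leukocytes carry. In the same libraries lymphocyte markers had a median log2 fold change of 1.56 (2.54 without day 0 replicate 2), and mitochondrially encoded genes took 8.29% and 9.31% of the counts, against 4.76% and 3.97% at day 0. Of 35 tuft identity genes, 7 fell and 1, Alox5ap, rose, against 9 and 1 adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.742 with an estimated correlation). That call was lost without day 0 replicate 1 (0.641) and day 14 replicate 1 (0.217), and Alox5ap had an edgeR adjusted p of 0.171 without day 14 replicate 2, 0.0971 without day 14 replicate 1, 0.0587 without day 0 replicate 2 and 0.0505 without day 6 replicate 1. Dclk1 had a log2 fold change of -0.46 and did not pass (edgeR adjusted p = 0.0621).

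In libraries with the same shift of lymphocyte and enterocyte markers (median log2 fold changes of 1.56, 2.54 without day 0 replicate 2, and -0.98), interferon-stimulated genes were called lower. Of 38, 14 fell at day 14 over all genes and 26 adjusted over the list alone, with none higher (camera adjusted p = 5.55e-12; adjusted p = 0.548 with an estimated correlation). Ifit3, an antiviral gene, fell from 69.3 ± 3.33 to 5.89 ± 0.09 CPM (SD, n = 2; edgeR adjusted p = 0.0202), with an adjusted p of 0.098 without day 14 replicate 1 and 0.142 without day 14 replicate 2. Its day 6 libraries stood at 37.0 and 4.89 CPM, and this spread between libraries of 1 day enters the test of every comparison. Oas2 had a log2 fold change of -1.805, with an edgeR adjusted p of 0.123 and 0.118 without day 14 replicates 1 and 2. Irf9 had one of -0.64, with an edgeR adjusted p of 0.0572 without day 0 replicate 2, and 0.0973 and 0.0989 without day 14 replicates 1 and 2. Of 19 class I genes, 3 fell, H2-Q1, H2-T3 and Nlrc5, and 5 did adjusted over the list alone (camera adjusted p = 5.53e-05; adjusted p = 0.548 with an estimated correlation). H2-Q1 lost its call without day 14 replicate 1 (edgeR adjusted p = 0.0565). H2-T3 lost it without day 0 replicate 1 (0.0664), day 14 replicate 1 (0.0839) and day 14 replicate 2 (0.104), and Nlrc5, an activator of class I genes, without day 0 replicate 1 (0.0664), day 0 replicate 2 (0.094), day 14 replicate 1 (0.176) and day 14 replicate 2 (0.182). Reads may be shared among class I copies, so H2-Q1 and H2-T3 are uncertain. Of 26 immediate-early genes, 1, Atf3, fell and 0 did adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.548 with an estimated correlation), and the call was lost without day 0 replicate 2 (0.308) and day 14 replicate 1 (0.0512). Atf3 had an edgeR adjusted p of 0.127 without day 0 replicate 2, 0.0517 without day 14 replicate 1 and 0.191 without day 14 replicate 2.

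The other lists were not called at day 14. In the type 2 cytokine list, 4 of 21 genes rose, Il33, Socs3, Tnfaip3 and Il2rg, and 1, Il17rb, fell (camera adjusted p = 0.328), and Socs3, an inhibitor of cytokine signalling, rose by 1.60 log2 units. Il33 lost its call without day 14 replicate 1 (edgeR adjusted p = 0.0539). Camera adjusted p was 0.126 for neuronal-type tuft genes, 0.436 for immune-type tuft genes, 0.93 for taste-type genes, 0.838 for acetylcholine genes (median -0.01, mean 0.26, test down) and 0.417 for ribosomal protein genes. It was 0.634 for the unfolded protein response, 0.0516 for goblet markers, 0.472 for Paneth markers (median -0.07, mean 0.04, test up), 0.696 for enteroendocrine, 0.714 for macrophage and 0.235 for stromal markers. Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 669 genes higher and 791 lower, of which 301 and 300 changed at least 2-fold. These counts were 446 and 465 without day 0 replicate 1, 247 and 234 without day 14 replicate 1, and 112 and 128 without day 14 replicate 2.

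The changes at day 6 and day 14 were set against each other, since both used the same day 0 libraries. In the same direction, 343 genes were called in both comparisons, 134 higher and 209 lower, and 2 genes were called in opposite directions. H2-Ab1, Cd74, Gsdmc2, Pla2g4c, Sucnr1 and Kit were among those higher on both days, and Anpep, Apoc3 and Fabp6 among those lower. In 40 simulations of unchanged groups that shared 2 simulated controls, 0.28 genes were called in the same direction on average. Independent lists of these sizes would share 12.3 higher and 21.3 lower. The simulation drew each gene apart from the others, controls included. Shifts of many genes together, like that of Paneth markers between the day 0 libraries, were not in it, so its counts may be too low. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.532. In simulation r had a mean of 0.504 and a maximum of 0.535, above the observed value. Their covariance was 0.298 against 0.0655 in simulation (maximum 0.074), a difference of 0.232. A split of the 2 control libraries would leave 1 per comparison and was not made. Part of the overlap and of the covariance may therefore come from the shared controls. The overlap was 155 without day 0 replicate 2, 162 and 153 without day 6 replicates 1 and 2, and 172 and 109 without day 14 replicates 1 and 2.

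The comparison of day 14 with day 6 asked which genes differed between the infected time points. Gkn1, Gkn2, Reg3g and the crypt base gene Olfm4 were higher at day 14, and P2rx1 was lower. Reg3g rose from 137 ± 60.6 to 1333 ± 69.5 CPM (SD, n = 2), a log2 fold change of 3.29 ± 0.28 (SE; edgeR adjusted p = 0.00425). P2rx1 fell from 222 ± 1.18 to 32.8 ± 10.7 CPM, a log2 fold change of -2.76 ± 0.21. Gkn1 had 0 counts at day 6 and was at least 358-fold higher at day 14, while Gkn2 had 2 counts at day 6, a ratio of 1130 (95% exact counting interval 313 to 9350). Olfm4 rose from 99.4 ± 12.9 to 494 ± 112 CPM (edgeR adjusted p = 0.00701; 0.0521 without day 6 replicate 1).

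Tuft cell genes were called lower at day 14 than at day 6: 7 of 35 tuft identity genes fell and 0 rose, and 26 fell adjusted over the list alone (camera adjusted p = 2.11e-15; adjusted p = 0.434 with an estimated correlation). In the same day 14 libraries, Paneth, goblet and lymphocyte markers had median log2 fold changes of 2.49, 1.19 and 1.69, and mitochondrially encoded genes took 8.29% and 9.31% of the counts, against 4.33% and 5.57% at day 6. Il17rb fell from 436 ± 8.33 to 181 ± 38.7 CPM (SD, n = 2; edgeR adjusted p = 0.0136), with an adjusted p of 0.094 without day 6 replicate 1 and 0.112 without day 14 replicate 1. Dclk1 fell from 2211 ± 36.4 to 1347 ± 126 CPM (edgeR adjusted p = 0.041), with an adjusted p of 0.246 and 0.0799 without day 6 replicates 1 and 2, and 0.274 and 0.116 without day 14 replicates 1 and 2. Of 16 neuronal-type tuft genes, 5 fell, Gng13, Dclk1, Folr1, Inpp5j and Rgs2, and 9 did adjusted over the list alone (camera adjusted p = 6.12e-08; adjusted p = 0.434 with an estimated correlation). Folr1, a folate receptor, had an edgeR adjusted p of 0.121 without day 6 replicate 1, 0.204 without day 14 replicate 1 and 0.0948 without day 14 replicate 2. Of 23 immune-type tuft genes, 2 fell, Cd300lf and Il17rb, against 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000842; adjusted p = 0.548 with an estimated correlation). Of 15 taste-type genes, 2 fell, Gng13 and Plcb2, and 1, Vmn2r26, rose, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.498 with an estimated correlation), and the call was lost without day 14 replicate 1 (0.0559). Vmn2r26 had an edgeR adjusted p of 0.131 and 0.0501 without day 6 replicates 1 and 2, and 0.167 and 0.0625 without day 14 replicates 1 and 2. Glycolysis genes, with 0 of 18 past the test and 8 lower and 1 higher adjusted over the list alone, were called lower (camera adjusted p = 0.000579; adjusted p = 0.548 with an estimated correlation). Interferon-stimulated genes, with 0 of 38 past the test both ways, were called lower (camera adjusted p = 1.94e-07; adjusted p = 0.593 with an estimated correlation), and the direction turned without day 6 replicate 1 (0.589). Class I genes, with 0 of 19 past the test both ways, were called lower (camera adjusted p = 0.00404; adjusted p = 0.652 with an estimated correlation), a call lost without day 6 replicate 1 (0.867) and day 14 replicate 1 (0.0914).

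Camera called 8 lists of crypt, secretory, antimicrobial, class II and response genes higher at day 14 than at day 6, none of them with an estimated correlation (adjusted p from 0.298 to 0.502). Of 13 stem cell markers, 6 rose, against 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 9.43e-09; adjusted p = 0.298 with an estimated correlation). Of 42 cell cycle genes, 3 rose, Mcm6, Ccnb1 and Nusap1, and 33 did adjusted over the list alone (camera adjusted p = 1.11e-16; adjusted p = 0.502 with an estimated correlation). Of 18 Paneth markers, 2 rose, Itln1 and Defa39, and 17 did adjusted over the list alone (camera adjusted p = 2.51e-15; adjusted p = 0.434 with an estimated correlation). Of 15 goblet markers, 1, Ccl6, rose and 5 did adjusted over the list alone (camera adjusted p = 3.85e-06; adjusted p = 0.502 with an estimated correlation). Of 15 antimicrobial genes, 5 rose, Reg3b, Reg3g, Reg4, Pigr and Duoxa2, and 8 did adjusted over the list alone (camera adjusted p = 3.78e-11; adjusted p = 0.298 with an estimated correlation). In the class II list, 3 of 8 genes rose, H2-Eb1, Cd74 and H2-Ab1, and 7 did adjusted over the list alone (camera adjusted p = 8.78e-09; adjusted p = 0.346 with an estimated correlation), beside a median log2 fold change of 1.69 for lymphocyte markers. In the IL-13 list, 4 of 23 genes rose, Gsdmc4, Gsdmc2, Itln1 and Mptx2, against 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.57e-09; adjusted p = 0.502 with an estimated correlation). In the fetal-like repair list, 4 of 18 genes rose, Il33, Anxa5, Clu and S100a6, against 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.32e-09; adjusted p = 0.434 with an estimated correlation). Without day 6 replicate 1, the edgeR adjusted p was 0.211 for Mcm6, 0.287 for Defa39, 0.263 for Ccl6, 0.094 for H2-Eb1, 0.165 for Gsdmc2 and 0.0702 for Clu. Without day 14 replicate 1, it was 0.161 for Mcm6, 0.253 for Defa39, 0.228 for Ccl6, 0.109 for H2-Eb1, 0.166 for Gsdmc2 and 0.109 for Clu. Without day 14 replicate 2, it was 0.127 for Mcm6, 0.145 for Defa39, 0.147 for Ccl6 and 0.0756 for H2-Eb1, and without day 6 replicate 2 it was 0.0922 for Defa39.

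Mitochondrially encoded genes were called higher at day 14 than at day 6, 4 of 13 over all genes, mt-Co1, mt-Co2, mt-Co3 and mt-Nd6, and 13 adjusted over the list alone (camera adjusted p = 1.24e-11; adjusted p = 0.434 with an estimated correlation). Of 16 lymphocyte markers, 4 rose, Nkg7, Gzma, Ccl5 and Cd7, and 10 did adjusted over the list alone (camera adjusted p = 2.3e-09; adjusted p = 0.434 with an estimated correlation). Of 6 genes of the granulocyte list, 2 rose, the mast cell genes Mcpt1 and Mcpt2, against 3 higher and 1 lower adjusted over the list alone. Camera called the list higher (adjusted p = 0.0026, and 0.346 with an estimated correlation), with a median log2 fold change of 0.09 and a mean of 2.015. Ribosomal protein genes, with 0 of 76 past the test both ways, were called higher (camera adjusted p = 0.000625; adjusted p = 0.745 with an estimated correlation), a call lost without day 14 replicate 1 (0.348). Enteroendocrine markers were called higher (camera adjusted p = 0.0388; adjusted p = 0.434 with an estimated correlation), a call lost without day 14 replicate 1 (0.0559), although the single member of 20 past the test, the secretin gene Sct, fell, against 5 higher and 1 lower adjusted over the list alone. Sct had an edgeR adjusted p of 0.321 without day 6 replicate 1, 0.233 without day 14 replicate 1 and 0.193 without day 14 replicate 2. Without day 6 replicate 1, day 14 replicate 1 and day 14 replicate 2, it was 0.184, 0.167 and 0.102 for mt-Nd6, 0.187, 0.141 and 0.123 for Gzma, and 0.0521, 0.112 and 0.0755 for Mcpt1.

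The other lists were not called between day 6 and day 14. Camera adjusted p was 0.2 for eicosanoid genes, 0.959 for acetylcholine genes, 0.588 for type 2 cytokine components, 0.696 for nuclear oxidative phosphorylation and 0.373 for cholesterol synthesis (median 0.004, mean -0.05, test down). It was 0.224 for the unfolded protein response, 0.958 for immediate-early genes (median -0.03, mean 0.125, test down), 0.417 for enterocyte markers (median 0.19, mean -0.02, test up), 0.171 for macrophage markers and 0.271 for stromal and red blood cell markers. Pou2f3, Il25 and Siglecf had edgeR adjusted p of 0.0598, 0.0813 and 0.15. Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 159 genes higher and 132 lower, of which 106 and 57 changed at least 2-fold. These counts were 573 and 340 without day 0 replicate 1, 548 and 334 without day 0 replicate 2, 8 and 6 without day 6 replicate 1, 87 and 151 without day 6 replicate 2, 5 and 1 without day 14 replicate 1, and 18 and 7 without day 14 replicate 2.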

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

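The test on stomach gland genes was set before its result was seen, and the share counting Muc6 and the tests on proximal and distal genes, on Fabp6 and on Paneth genes were chosen after the results were seen. The genes below differ in their change from day 0 between day 14 and day 6, by edgeR's quasi-likelihood test of that difference with Benjamini-Hochberg adjustment. Each value is the log2 fold change of day 14 against day 6.

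Of the genes that kept this call whichever library was left out, Gkn1 was 11.91 higher, Gkn2 9.93, Tff1 7.62 and Reg3g 3.29, and P2rx1 had -2.76. The fitted values of Gkn1 and Gkn2 depend on the prior count and are no bounds. Gkn2 was 9.05 without day 6 replicate 1, 12.90 without day 6 replicate 2 and 9.20 without day 14 replicate 2, and Tff1 was 9.83, 6.75 and 6.93 without the same libraries. Agt, angiotensinogen, had -2.05 (edgeR adjusted p = 0.0793 without day 14 replicate 1) and Socs3 had 2.22 (0.0825 without that library). Olfm4 had 2.31 (0.0521 without day 6 replicate 1). Tff2 had 5.43, with an edgeR adjusted p of 0.112 without day 14 replicate 1 and 0.0688 without day 14 replicate 2, and was 7.69 without day 6 replicate 1 and 4.56 without day 6 replicate 2. Marcksl1 had -1.63 (0.112 and 0.0643 without day 14 replicates 1 and 2).

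Without day 6 replicate 1 and without day 14 replicate 1, the edgeR adjusted p was 0.094 and 0.112 for Il17rb (-1.27), 0.165 and 0.166 for Gsdmc2 (1.92) and 0.0702 and 0.109 for Clu (2.69). Without day 6 replicate 1, day 14 replicate 1 and day 14 replicate 2, it was 0.273, 0.253 and 0.133 for Defa34 (4.40; 3.66 and 6.08 without day 6 replicates 1 and 2), 0.221, 0.253 and 0.159 for Ltb (-1.71), 0.121, 0.204 and 0.0948 for Folr1 (-1.39) and 0.094, 0.109 and 0.0756 for H2-Eb1 (1.73). In that order it was 0.211, 0.161 and 0.127 for Mcm6 (1.204), 0.184, 0.167 and 0.102 for mt-Nd6 (0.98), 0.263, 0.228 and 0.147 for Ccl6 (1.98), 0.321, 0.233 and 0.193 for Sct (-0.83) and 0.187, 0.141 and 0.123 for Gzma (1.81). For Mcpt1 (7.42; 1 count at day 6 against 187, ratio 220, 95% exact counting interval 39.0 to 8740) it was 0.0521, 0.112 and 0.0755, with fitted values of 9.59 and 6.55 without day 6 replicates 1 and 2. Without day 6 replicates 1 and 2 and day 14 replicates 1 and 2, it was 0.13, 0.0552, 0.253 and 0.128 for Pck1 (-1.85), 0.131, 0.0501, 0.167 and 0.0625 for Vmn2r26 (1.28) and 0.0521, 0.0528, 0.204 and 0.0667 for Cyp3a11 (-1.39). It was 0.287, 0.0922, 0.253 and 0.145 for Defa39 (2.48) and 0.246, 0.0799, 0.274 and 0.116 for Dclk1 (-0.72).

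Gkn1, Gkn2, Tff1 and Tff2, genes of mucous cells of the stomach, were detected at day 14 and stood at 0 or low levels before. Tff2 was already at 1.62 and 0.18 CPM in the day 6 libraries. Stomach tissue with acid- and enzyme-making glands is argued against. The table held 6 of the genes listed for it, Atp4a and Pgc among them. In day 14 replicates 1 and 2 they summed to 3.0% and 2.0% of the summed CPM of the 4 mucous cell genes. Both shares lay under the bound of 5% set beforehand. Muc5ac and Gast, also among the 6, are not genes of acid- or enzyme-making cells. Muc6, a mucous gland gene of stomach and duodenum outside that list, stood at 53.0 and 2.47 CPM in these libraries. Counting it, the shares were 48.1% and 3.2%, so mucous gland tissue stays open for replicate 1. On surface mucosa of the stomach, acid- and enzyme-making gland genes cannot speak. Muc5ac, a mucin gene of surface mucous cells, stood at 0.87 and 0.16 CPM in day 14 replicates 1 and 2, far below Gkn2 at 30.97 and 71.4 CPM. Surface mucosa was not tested apart, and 1 gene with few counts does not settle it, so it stays open for both libraries. More proximal intestine at day 14 cannot be told apart from the fall of enterocyte genes. The median log2 fold change was 0.65 for 6 proximal genes, Muc6 among them and 0 past the test. Pdx1, Gata4 and Onecut2 had -0.225, 0.179 and 0.123, while Cybrd1, Slc40a1 and Muc6 had 1.34, 1.13 and 3.32. The median was -1.49 for 7 distal genes and -0.96 for 25 enterocyte markers. Most of the difference of 2.14 between proximal and distal genes (exact two-sided permutation p = 0.0117) thus lay in the distal genes. A response of the tissue to infection stays open and was not tested apart from region.

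Fabp6, a gene of ileal enterocytes, which an EpCAM gate would keep and a SiglecF gate would remove, was lower at day 6 and day 14, with 104 and 474 CPM in the day 0 libraries. Fabp6 was picked for its fall, so its rank says nothing, but the size of the gap argues against fewer admixed enterocytes in general as the whole cause: its log2 fold change minus that of the marker that fell most among 25 others was -4.38 at day 6 and -6.97 at day 14, and at the least -2.98 with a library left out (day 0 replicate 2, day 6). Less distal intestine may contribute, and the medians cannot tell it apart from the fall of enterocyte genes. The median of 7 distal genes lay below that of 25 enterocyte markers at day 14 by a difference of -0.53 (two-sided permutation p = 0.0153). Without Cubn, whose fall had been seen, the difference was -0.42 (two-sided permutation p = 0.111). Slc10a2, the ileal bile acid transporter, stood at 1.58 and 3.56 CPM at day 0 and 0.10 and 0.14 CPM at day 6. Its log2 fold change was -4.40 at day 6 and -6.25 at day 14 (edgeR adjusted p = 0.0259 and 0.0105). Fgf15, another distal gene, had -5.325 and -6.493 (edgeR adjusted p = 0.0361 and 0.0182). Both fell more than any of the 25 enterocyte markers, but had few counts, so they do not settle the question. The other distal genes ran from -1.71 to -0.55 at day 6 and from -2.07 to -0.33 at day 14. Of the 7, 5 passed the test at day 6 and 6 at day 14. A biological fall of Fabp6 in these cells stays open and was not tested.

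Paneth cell genes were lower at day 6, and a difference in the share of admixed Paneth cells between libraries of 1 day is a candidate explanation. All 18 markers together had a median log2 ratio of 2.15 between day 0 replicate 2 and replicate 1, with an interquartile range of 0.52, which is a shift of 4.45-fold in most of them alike. An EpCAM gate would keep Paneth cells and a SiglecF gate would remove them. Between days, the libraries of day 6 (4.85 and 5.01 mean log2 CPM) also lay below day 0 replicate 1 (5.52), so a change with infection stays open and was not tested apart from this share.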

How the results depend on the processing

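The covariate and the counts rounded up were chosen after the data were seen. Counts of called genes (higher and lower for day 6 against day 0, day 14 against day 0, then day 14 against day 6) depended on the processing, and the cause was not tested beyond the fewer samples of the left-out fits, in which a lone library is assumed to vary like the other groups. With DESeq2 they were 673 and 678, 1085 and 1193, and 603 and 506. With no low-count filter they were 603 and 711, 1058 and 1162, and 688 and 466. Only the days compared gave 594 and 363 for day 14 against day 6. A 2-fold threshold left 103 and 191, 301 and 300, and 106 and 57. The Paneth covariate gave 10 and 42, 979 and 874, and 5 and 2. Without the abundant genes, the share higher at day 14 against day 6 was 45.9% in place of 54.6%. Leaving out 1 library gave 48 to 563 and 132 to 497, 112 to 637 and 128 to 758, and 5 to 573 and 1 to 340. The number of genes called in the same direction at day 6 and day 14 against day 0 was 715 with DESeq2, 684 with no filter, 44 with the covariate and 109 to 437 with 1 library left out. The replicate block gave 72 and 173, 404 and 505, 33 and 22, and an overlap of 165. Deviations of same-numbered libraries correlated across genes by 0.153, -0.134 and -0.035. These values give little sign that the numbers pair the libraries but cannot exclude it, and the labels do not say. All 55 list calls stood under the block.

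Directions turned for the uncalled genes and the 4 list tests named here, and the cause was not tested. With the covariate, log2 fold changes at day 6 were 0.006 for Trpm5, -0.075 for Il25, -0.03 for Alox5 and 0.91 for Mki67. At day 14 against day 0 they were 0.11 for Siglecf and 0.11 for Chat, and at day 14 against day 6 they were 0.089 for Epcam, 0.22 for Alox5, 0.25 for Hpgds, 0.038 for Chat and -0.42 for Mki67. The block gave 0.002 for Chat at day 14 against day 0, and Sucnr1 had -0.005 without the abundant genes at day 14 against day 6. With 1 library left out, Mki67 ran from -0.78 to 0.54 at day 6, and at day 14 against day 0 Siglecf ran from -0.29 to 0.25, Alox5 from -0.18 to 0.33, Ptgs1 from -0.23 to 0.32 and Chat from -0.25 to 0.26. At day 14 against day 6, Sucnr1 ran from -0.22 to 0.22 and Ly6a from -1.63 to 0.60. Camera adjusted p with 1 library left out ran from 5.16e-05 to 0.562 for the IL-13 list at day 6, where the direction turned at 0.466, from 1.66e-47 to 0.0467 for interferon-stimulated genes at day 6, from 4.33e-07 to 0.554 for goblet markers at day 6, and from 3.47e-61 to 0.589 for interferon-stimulated genes at day 14 against day 6. Of 3113 alternatives for single genes, 2601 kept direction and call, 428 lost the call, 61 gained it and 23 turned. Of 495 for lists, 358 kept both, 133 lost the call, 0 gained it and 4 turned, and 37 of 55 list calls stood in all 6 left-out fits. Depth limits genes with few counts, such as Gkn2 and Mcpt1 before day 14.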

Other observations

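The values below were chosen after they were seen, and no explanation of them was tested. Interferon-stimulated genes differed between the day 6 libraries. Ly6e, an interferon-induced surface protein gene, stood at 2019 and 1897 CPM at day 0, 1628 and 172 CPM at day 6, and 189 and 260 CPM at day 14. Oas2, an antiviral synthetase, stood at 1043 and 1116 CPM at day 0, 981 and 350 CPM at day 6, and 266 and 352 CPM at day 14.

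Cpe, carboxypeptidase E of endocrine cells, rose from 4.36 ± 0.47 to 51.7 ± 6.44 CPM at day 14 (SD, n = 2; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00241). Other enteroendocrine markers did not rise with it. Sct fell from 379 ± 32.9 to 202 ± 21.9 CPM and Chga stood at 28.3 and 28.2 CPM. The list was not called at day 14 against day 0 (camera adjusted p = 0.696), with 1 of 20 genes higher and 1 lower. Ctsc, which activates granzymes, rose from 82.2 ± 13.4 to 279 ± 27.5 CPM at day 14. Kcnj16, a potassium channel, rose at day 6 from 5.49 ± 0.04 to 21.3 ± 2.21 CPM.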
